A study of Mus musculus with 9 samples.

How the data were processed

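Messenger RNA was measured in T follicular helper (Tfh) cells of mouse Peyer's patches, the lymphoid tissue of the small intestine. Per the labels' protocols, cells carrying CD4, CXCR5 and PD1 were sorted by flow cytometry, and 300 pg of RNA per library went into a SMART-Seq low-input kit that does not mark the strand. Reads of a gene and of a partner on the opposite strand can therefore not be told apart. The 9 libraries fall into 2 groups, 5 from mice with 1 mutant Tgfbr1 allele (WT/mut, replicates 6 to 10) and 4 from wild-type littermates (WT, replicates 1, 3, 4 and 5). The labels give no sex, litter, sorting day or sequencing batch, do not say what the mutation is, and do not say that each library came from a separate animal, so p-values measure only the spread between these libraries.

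The deposited table holds expected counts per gene, which need not be whole. Per the submitters' processing notes, cutadapt 2.10, STAR 2.5.3, RSEM 1.3.0 and DESeq2 were used with the mm10 build; the annotation release is not given in the sources used here. Between 11.1% and 18.3% of all values in a library, zeros included, were not whole, so the share among values above 0 was higher. All values were rounded to whole numbers before any test. An expected count shares reads between near-identical genes by a model, so values of Apol9a and Apol9b, the hemoglobin genes, immunoglobulin segments, Ly6 family members and ribosomal protein genes are uncertain where the copies differ. Gene positions are those of GENCODE release M21 on GRCm38, the assembly of mm10. Of the 54146 gene identifiers in the table, 54079 were found in that annotation.

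All tests across genes used R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 (robust fit, TMM factors, no covariate, 5 against 4 libraries) on the 15521 genes that passed filterByExpr (minimum count 10, minimum total 15). P-values were adjusted by the Benjamini-Hochberg method over these genes, with a threshold of 0.05. Log2 fold changes are WT/mut over WT, and their SE is the absolute log2 fold change divided by the square root of F. Levels are CPM values (edgeR, library sizes scaled by TMM), given as mean ± SD over the libraries of a group. For a gene with no count in any WT library, the fold is a lower bound against a floor of 3 counts summed over the WT libraries. Intervals and floors cover counting error only, since the library kit adds no molecular identifiers.

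Gene lists (33) were fixed before the data were examined, as were the tests and all alternatives not said to be chosen later. The 31 lists with at least 5 tested genes were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 31. Beside it stand camera with an estimated correlation, fry, and the number of members that pass when adjusted over the list alone. Shares of counts and principal components (500 most variable genes, log2 CPM with a prior count of 2) were compared by exact two-sided permutation tests. These ran over all 126 splits of 9 libraries into 5 and 4, in which the smallest possible p is 0.00794. At that p, a single one of 9 measures or of 31 lists would still not pass after adjustment. The text names Tgfbr1, up to 12 called genes in each direction with the largest fold change and no overlap between groups (leaving out predicted genes, pseudogenes, ribosomal protein genes and receptor segments, of which 0 were called), 23 of 24 genes of Tfh, helper and TGF-beta biology fixed by name, and the 4 members of lowest p from lists that were called or that held a called gene. Further members that passed over their list alone, and other genes outside this rule, were chosen after their values were seen.

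Alternatives were DESeq2 1.42.0, limma-voom with and without library weights, other size factors, filters and thresholds, a non-robust fit, 1 surrogate variable (sva 3.50.0), the number of detected genes as a covariate, leaving out receptor segments with Xist and Y-linked genes, and leaving out each library in turn. A planned covariate of Y-linked minus Xist expression was not run, because all 9 libraries were alike in it. Xist had 1818 to 6072 counts per library, and the 4 Y-linked genes summed to between 0 and 4.

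The main test was tested on simulated counts of 15521 genes, drawn from the real means, library sizes and dispersions of this comparison with 50 genes changed at each of 4 fold sizes. It recovered 10 of 50 genes changed 1.5-fold, 38 of 50 changed 2-fold, 48 of 50 changed 4-fold and 49 of 50 changed 8-fold, with 4 unchanged genes among 149 calls. DESeq2 on the same counts made 194 calls, of which 34 were unchanged genes. The changed genes were drawn only from genes above a minimum mean CPM. Recovery at lower levels, such as those of Tek, Stard8, Lrrn1 and Trpm6, was therefore not measured. In the simulation genes vary independently, and camera called 0 of 31 lists when nothing was changed.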

Results

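The study compared Tfh cells from Peyer's patches of mice with 1 mutant and 1 wild-type Tgfbr1 allele (WT/mut, n = 5 libraries) with those of wild-type littermates (WT, n = 4). Tfh cells help B cells in germinal centres, and Tgfbr1 encodes a subunit of the receptor for TGF-beta. The series' title places the comparison in a study of TGF-beta signals to T cells and of Tfh cells with type 2 features. Total counts per library lay between 29488783 and 43872686. Of the 54146 genes in the table, 34361 had a count in at least 1 library and 15521 were tested. None of the 16 pairs of libraries within a group agreed within sampling noise, with mean chi-square values per gene between 28.8 and 232.

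Tgfbr1 itself (ENSMUSG00000007613.15, chromosome 4, 47353222 to 47414931 on GRCm38) was measured at 73.6 ± 16.5 CPM (SD, n = 5) in WT/mut and at 77.0 ± 20.2 CPM (SD, n = 4) in WT cells. Its log2 fold change was -0.07 ± 0.21 (SE), with an edgeR adjusted p of 0.921 and an exact two-sided permutation p of 0.802. The sign turned to 0.06 without WT/mut replicate 10 and to 0.07 without WT replicate 5, so the table gives no direction. Counts per gene do not separate the mutant from the wild-type allele, and a mutation that leaves the transcript in place would not show here. The receptor partner Tgfbr2 (0.17 ± 0.21, adjusted p = 0.747), the signal transducer Smad3 (0.19 ± 0.33, adjusted p = 0.834) and the ligand gene Tgfb1 (-0.05 ± 0.13, adjusted p = 0.890) also did not pass the threshold.

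In WT/mut cells, 14 genes fell and 5 rose (edgeR, adjusted p under 0.05). The lowest p belonged to Sardh, which encodes the mitochondrial enzyme sarcosine dehydrogenase (ENSMUSG00000009614.16, chromosome 2, 27188393 to 27248337). It stood at 6.04 ± 0.81 CPM in WT/mut and 32.1 ± 6.6 CPM in WT cells, a log2 fold change of -2.41 ± 0.18 (adjusted p = 0.000397). Fam3c, which encodes a secreted cytokine-like protein, fell by 1.09 on the log2 scale (SE 0.11, adjusted p = 0.00487). Ctsw, the gene of the lymphocyte protease cathepsin W, fell by 1.70 (SE 0.20, adjusted p = 0.0142), and Kit, the receptor for stem cell factor, fell by 2.09 (SE 0.31, adjusted p = 0.0334), from 42.1 ± 11.2 to 9.93 ± 3.89 CPM. Klf10, a transcription factor known as an early TGF-beta target, fell by 1.02 (SE 0.15, adjusted p = 0.0344), from 162 ± 41 to 80.0 ± 8.3 CPM. The magnesium channel gene Trpm6 (-3.17 ± 0.49), the adhesion gene Nectin3 (-1.36 ± 0.17), Apol9b (-1.39 ± 0.18), Tmem176a (-0.94 ± 0.14), Cldnd1 (-0.84 ± 0.13) and the ceramide kinase gene Cerk (-0.79 ± 0.13) also fell, with adjusted p between 0.0237 and 0.0441. Apol9b shares most of its sequence with Apol9a, which was also lower (-1.21 ± 0.23, adjusted p = 0.0864, chosen after its value was seen), and the split of reads between them is uncertain. Lrrn1 had 179 counts over the WT libraries and 1 over the WT/mut libraries, a ratio of 194 with a counting interval from 34.4 to 7717. The called genes outside the naming rule were Rgs10 (-0.65 ± 0.08) and Tubb2a (-0.64 ± 0.10), both lower.

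Ly6a, the gene of the surface protein Sca-1, rose by 1.95 ± 0.29 on the log2 scale, from 10.6 ± 2.9 to 40.9 ± 15.6 CPM (adjusted p = 0.0334). Cpt1a, which controls entry of fatty acids into mitochondria for oxidation, rose by 0.83 ± 0.12, from 105 ± 11 to 187 ± 26.5 CPM (adjusted p = 0.0334). Mlec, the gene of the endoplasmic reticulum lectin malectin, rose by 0.73 ± 0.10 (adjusted p = 0.0321). Tek, an endothelial receptor gene, had 252 counts over the WT/mut libraries and none in WT, at least 77.4-fold higher. Stard8, which encodes a protein with a lipid-binding START domain, had 191 counts against none, at least 58.7-fold higher. All 19 called genes had separate CPM ranges in the 2 groups. Over all tested genes this held for 693, or 4.46%, against 1.59% by chance. The count of 19 rested on every library but 1. It was 2 without WT/mut replicate 6, 2 without 7, 5 without 8, 4 without 9, 5 without 10, 6 without WT replicate 1, 2 without 3, 8 without 5 and 23 without WT replicate 4, while Sardh and Fam3c passed in all 9 of these fits. Covariates ended more calls. With the number of detected genes or the epithelial marker share, Sardh was the 1 gene called, and Fam3c did not pass at -1.07 ± 0.13 (adjusted p = 0.0501) and -1.14 ± 0.14 (adjusted p = 0.0745), close to its value without a covariate. With the plasma cell marker share edgeR called 0 genes. At an unadjusted p under 0.05 there were 496, fewer than the 776 expected by chance and the 1886 without a covariate. The call of Sardh ended in that fit at a fold that had not shrunk, with a larger error (-2.57 ± 0.31, adjusted p = 0.135). Fam3c was at -0.78 ± 0.16 in that fit (adjusted p = 0.750). Fam3c also did not pass without WT/mut replicates 7 and 9 together, where its value was -1.09 ± 0.14 (adjusted p = 0.154). The marker shares and the omission of these 2 libraries were chosen after the data were seen. With library size as the only scaling, 8 genes rose and 14 fell, and DESeq2 called 486 genes, among them all 19.

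**Figure D1:**
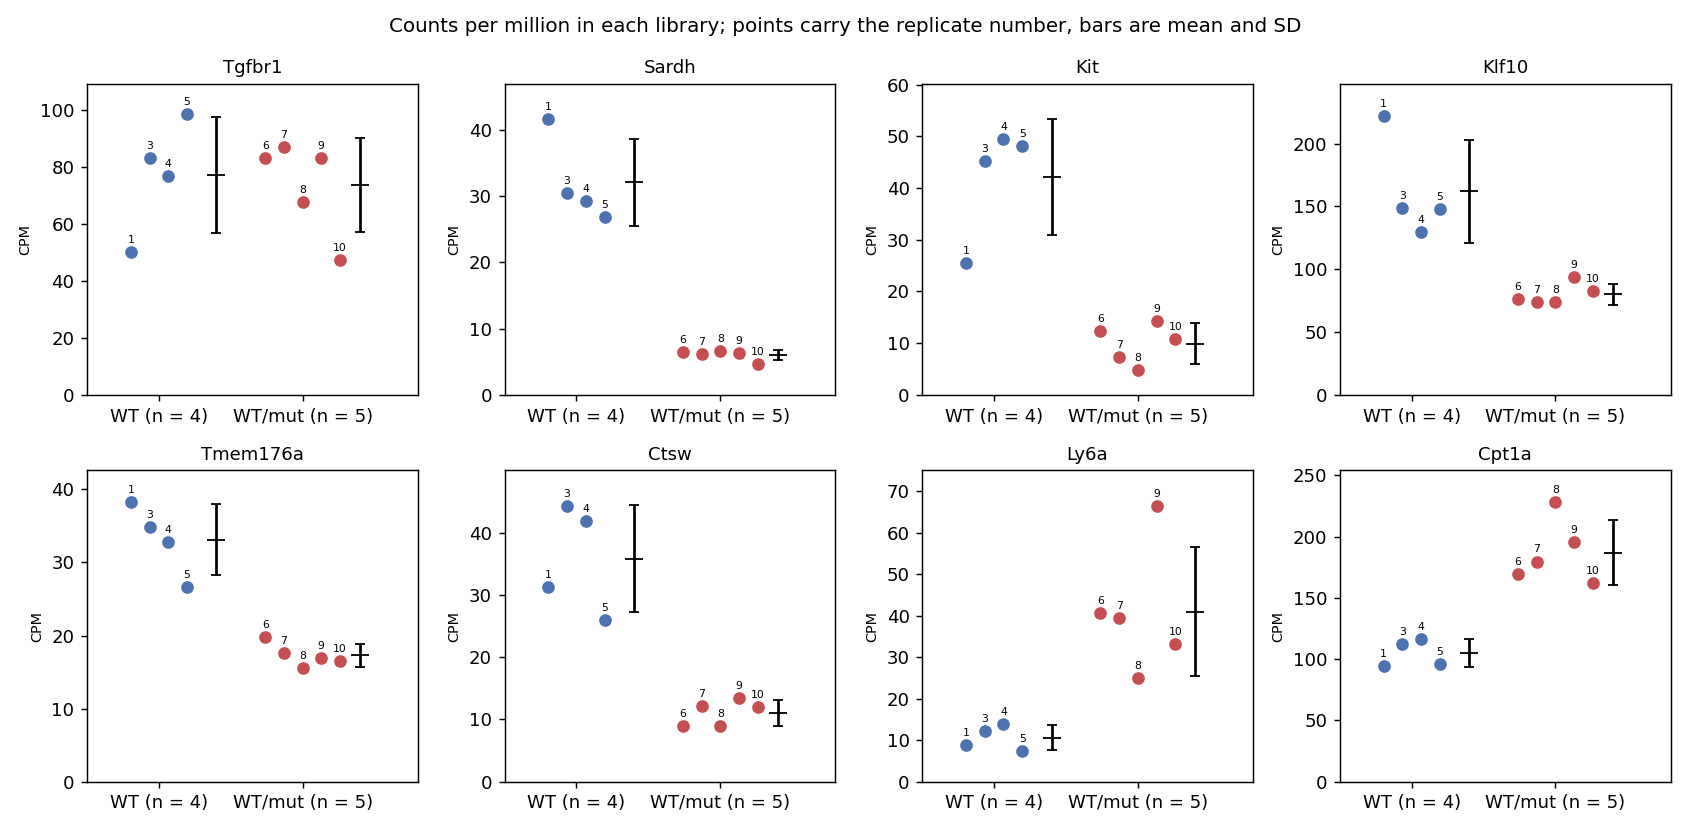
CPM (linear axes from 0) of Tgfbr1, 5 genes that fell and 2 that rose in WT/mut cells; each point is 1 library with its replicate number, and the bar gives the mean and SD of the group. The groups overlap for Tgfbr1 and are apart for the other 7 genes, as for Sardh, at 6.04 ± 0.81 CPM in WT/mut and 32.1 ± 6.6 CPM in WT libraries.

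Genes known to respond to TGF-beta were lower in WT/mut cells. Of 24 tested members of the fixed list, 18 had a negative and 6 a positive fold change, with a median log2 fold change of -0.26 (camera adjusted p = 1.7e-05). With an estimated correlation the list did not pass (adjusted p = 0.0835). Klf10 was the member called over all genes, and 7 fell when adjusted over the list alone, namely Klf10, Pmepa1, Skil, Ldlrad4, Cdkn1a, Smad7 and Gpr15. The values of 3 inhibitors of the pathway were -0.70 ± 0.14 for Pmepa1 (adjusted p = 0.0922 over all genes), -0.73 ± 0.15 for Skil (adjusted p = 0.104) and -0.80 ± 0.24 for Smad7 (adjusted p = 0.274). Ldlrad4 stood at -0.46 ± 0.12 (adjusted p = 0.226), and the integrin gene Itgae at -0.53 ± 0.22 (adjusted p = 0.371). The 24 tested genes of the pathway's own components did not shift (median -0.05, adjusted p = 0.994), with fry and camera differing in sign. The mean log2 CPM of the response list per library overlapped between the groups (exact permutation p = 0.222, adjusted p = 0.420, a test chosen after the data were seen).

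The type 17 helper list fell as well, and it was the list that kept its call with an estimated correlation (adjusted p = 2.17e-06 with the preset and 0.0354 with the estimated one). By exact permutation of its mean log2 CPM per library it did not pass after adjustment (p = 0.0317, adjusted p = 0.141), which no list could do alone. Of its 14 tested members, 11 had a negative fold change, and the median was -0.47. Tmem176a was called over all genes. In all, 6 members fell when adjusted over the list alone, among them Bhlhe40 (-0.51 ± 0.10, adjusted p = 0.0922 over all genes), Tmem176b (-0.71 ± 0.16, adjusted p = 0.149), Rora (-0.32 ± 0.10, adjusted p = 0.274) and Il1r1 (-0.51 ± 0.15, adjusted p = 0.278). Tmem176a and Tmem176b overlap on opposite strands of chromosome 6. Since the kit does not mark the strand, their values are not independent. Il17a had 2 counts in WT/mut replicate 7 and none elsewhere, which is under the floor of 3 counts.

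The Tfh list as a whole did not pass (32 members, median -0.05, camera adjusted p = 0.185), although it did without WT replicate 1 (adjusted p = 0.0176, in a range from 0.0176 to 0.668 over the fits without 1 library), with 1 surrogate variable and with the plasma cell marker share as a covariate, which makes 3 of 20 alternatives. The lineage factor Bcl6 (0.17 ± 0.11, adjusted p = 0.526) and both sorting markers, Cxcr5 (-0.16 ± 0.08, adjusted p = 0.451) and Pdcd1 (-0.03 ± 0.13, adjusted p = 0.934), did not pass. Within the list 3 members fell when adjusted over the list alone. They were the costimulatory receptor gene Icos, at 807 ± 71 CPM in WT/mut and 1154 ± 84 CPM in WT (-0.52 ± 0.09, adjusted p = 0.0721 over all genes), the cytokine gene Il21, at 448 ± 51 and 657 ± 104 CPM (-0.55 ± 0.12, adjusted p = 0.142), and Tox (-0.37 ± 0.08, adjusted p = 0.137). For each of these 3 the CPM ranges of the groups did not overlap. Cd40lg stood at -0.28 ± 0.11 (adjusted p = 0.368).

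Il4, the leading type 2 cytokine gene, was measured at 46.6 ± 8.7 CPM in WT/mut and 27.2 ± 4.2 CPM in WT cells, with no overlap (0.78 ± 0.16). It did not pass over all genes (edgeR adjusted p = 0.106) and passed over its list alone (adjusted p = 0.0105); DESeq2 called it (adjusted p = 0.000802). The type 2 list as a whole did not shift in 1 direction (20 members, median -0.07, camera adjusted p = 0.994), since Il4 and Il4ra rose and Csf2 and Cd200r1 fell over the list alone. Gata3, the type 2 lineage factor, stood at 0.31 ± 0.11 (adjusted p = 0.325). Il5 had 29 counts in WT/mut replicate 6 and none in the other 8 libraries, and Il13 had 1 count in WT/mut replicate 7, under the floor of 3 counts. The type 1 list (22 members, adjusted p = 0.994), Tbx21 (0.08 ± 0.25, adjusted p = 0.916) and Ifng (-0.32 ± 0.69, adjusted p = 0.877) did not pass. Of the regulatory T cell list (25 members, adjusted p = 0.754), Il1r2 fell over the list alone. Foxp3 (0.36 ± 0.23, adjusted p = 0.529), Il2ra (0.16 ± 0.42, adjusted p = 0.903), Ctla4 (0.16 ± 0.12, adjusted p = 0.597) and Il10 (-0.55 ± 0.90, adjusted p = 0.825) did not pass. The signs of Il10 and Ifng turned without WT replicate 3.

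**Figure D2:**
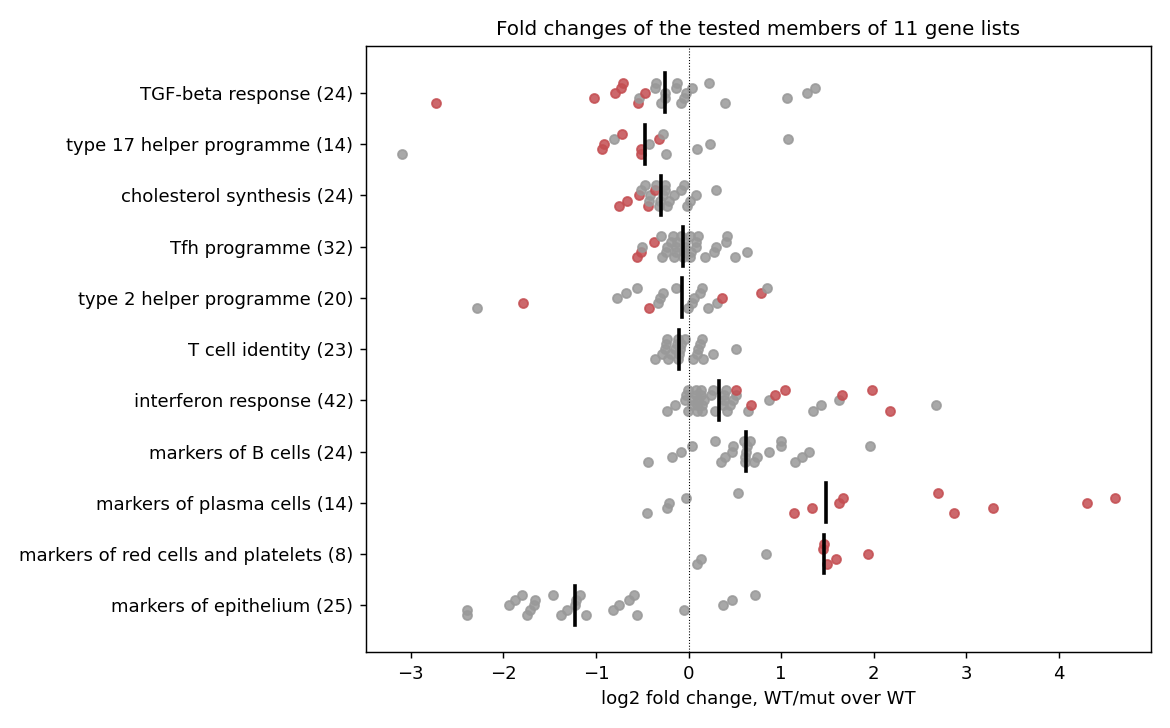
Log2 fold change (WT/mut over WT, horizontal axis) of each tested member of 11 gene lists, with the number of members in brackets; red points pass at an adjusted p under 0.05 over the list alone, grey points do not, and black bars are list medians. The median of the TGF-beta response list lies at -0.26 and that of the type 17 list at -0.47, while the plasma cell list lies at 1.48 and the epithelial list at -1.22.

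Among metabolic groups, cholesterol synthesis genes fell, with 21 of 24 members negative and a median of -0.29 (camera adjusted p = 3.23e-06, but adjusted p = 0.0835 with an estimated correlation). Over the list alone 5 members fell, including Msmo1 (-0.75 ± 0.15), Sqle (-0.66 ± 0.16), Fdps (-0.43 ± 0.11) and Cyp51 (-0.53 ± 0.14), with adjusted p between 0.104 and 0.218 over all genes. The interferon response list rose, with 36 of 42 members positive and a median of 0.33 (adjusted p = 1.62e-07, and adjusted p = 0.329 with an estimated correlation). Over the list alone 7 members rose, including Rtp4 (1.65 ± 0.34), Ifi27l2a (0.67 ± 0.16), Oas1a (0.93 ± 0.23) and Ifit2 (0.51 ± 0.13), with adjusted p between 0.106 and 0.218 over all genes. Glycolysis and hypoxia genes rose (median 0.17, adjusted p = 0.00271, and adjusted p = 0.329 with an estimated correlation). Their members of lowest p were P4ha1 (0.68 ± 0.16), Gpi1 (0.46 ± 0.12), Egln1 (0.36 ± 0.10) and Pfkp (0.29 ± 0.09), of which the first 3 passed over the list alone. With the epithelial marker share as a covariate the list did not pass (adjusted p = 0.0642).

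The ribosomal protein list rose, with all 43 members positive (median 0.38, adjusted p = 5.43e-13), with values such as 0.38 ± 0.13 for Rps16, 0.56 ± 0.20 for Rps7, 0.51 ± 0.18 for Rps19 and 0.73 ± 0.28 for Rps12, but adjusted p = 0.439 with an estimated correlation. The proliferation list rose (39 of 45 members positive, median 0.30, adjusted p = 0.000147), with adjusted p = 0.532 with an estimated correlation. Uhrf1 (0.66 ± 0.21), Bub1b (0.72 ± 0.26), Ccnb2 (0.64 ± 0.25) and Kif11 (0.99 ± 0.40) had its lowest p. WT/mut replicate 9 was highest of the 9 libraries in mean log2 CPM of both lists, at 7.42 for ribosomal proteins, against 6.91 at most in the others, and at 4.77 for proliferation, against 4.10 at most. Without it both lists passed (adjusted p = 7.72e-09 and 0.0342). The oxidative phosphorylation list fell slightly (47 of 60 members negative, median -0.13, adjusted p = 0.00237, and adjusted p = 0.585 with an estimated correlation), with the lowest p for Uqcr11 (-0.34 ± 0.15), Ndufb8 (-0.40 ± 0.18), Uqcrc1 (-0.45 ± 0.21) and Ndufv2 (-0.35 ± 0.16), and did not pass without WT replicate 5 (adjusted p = 0.0602) or with 1 surrogate variable (adjusted p = 0.0662). With the plasma cell marker share as a covariate this list passed in the other direction (adjusted p = 0.00419). The T cell receptor and immediate early list fell (median -0.13, adjusted p = 0.0282, and adjusted p = 0.434 with an estimated correlation). Its members went both ways, with Egr2 at -0.39 ± 0.10, Egr1 at -0.39 ± 0.11, Nr4a1 at -0.66 ± 0.20 and Cd44 at 0.41 ± 0.13. It did not pass without WT/mut replicates 7 or 9 or WT replicates 3 or 4, with adjusted p up to 0.184, and it passed in 7 of all 20 alternatives. With edgeR 0 members of these 4 lists passed when adjusted over the list alone or over all genes. At an unadjusted p under 0.05 there were 13 ribosomal and 7 proliferation genes, all higher, 2 oxidative phosphorylation genes, both lower, and 2 higher and 7 lower genes of the immediate early list. Over all 15521 tested genes 1886 reached that level, which is the baseline for these counts and for those of the marker lists below.

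Markers of cells outside the gate also differed. Plasma cell markers rose (10 of 14 positive, median 1.48, camera adjusted p = 1.97e-07, and adjusted p = 0.159 with an estimated correlation), and 9 passed over the list alone. Jchain, which joins secreted antibodies, was at 164 ± 86 CPM in WT/mut and 22.6 ± 13.6 CPM in WT (2.86 ± 0.53, adjusted p = 0.0904 over all genes). The antibody genes Igha (3.29 ± 0.66), Igkc (1.63 ± 0.45) and Iglc1 (4.30 ± 1.20) had adjusted p between 0.106 and 0.260. The value of Iglc1 rested in part on WT/mut replicate 6, at 125 CPM, and was 2.60 without it. Without WT replicate 4, Igkc passed over all genes (2.35, adjusted p = 0.0143), and Igha was at 3.95 (adjusted p = 0.0829). B cell markers rose (21 of 24 positive, median 0.62, adjusted p = 1.7e-05, and adjusted p = 0.441 with an estimated correlation), with Spib at 1.96 ± 0.66, Cr2 at 1.3 ± 0.49 and Cd79a at 0.99 ± 0.40, while Cd72 was at -0.44 ± 0.18. Spib was at 2.72 without WT replicate 4. With edgeR 0 B cell markers passed over the list alone or over all genes, and 6 higher and 1 lower had an unadjusted p under 0.05. The germinal centre B cell list rose (median 0.97, adjusted p = 0.00505, and adjusted p = 0.434 with an estimated correlation), with Gpr137b at 0.49 ± 0.14, Basp1 at 0.97 ± 0.37 and Nuggc at 2.31 ± 0.90, and Mef2b going the other way at -0.87 ± 0.22. With the plasma cell marker share as a covariate this list and the plasma cell list did not pass (adjusted p = 0.157 and 0.116). Red cell and platelet markers rose (8 of 8 positive, median 1.46, adjusted p = 6.52e-08, and adjusted p = 0.0835 with an estimated correlation), led by Hbb-bs (1.59 ± 0.31), Alas2 (1.5 ± 0.31), Hba-a2 (1.45 ± 0.31) and Hba-a1 (1.47 ± 0.33). Stromal and endothelial markers rose (10 of 13 positive, median 0.29 with Tek at its fitted value or at its bound, adjusted p = 0.000901, and adjusted p = 0.439 with an estimated correlation). Tek was the only member of this list that passed over the list alone. The next members by p were Madcam1 (2.71 ± 0.94), Col4a1 (1.25 ± 1.44) and Pecam1 (0.09 ± 0.13), with edgeR adjusted p of 0.323, 0.743 and 0.791 over all genes. Col4a1 was at -0.0427 without WT/mut replicate 7 and at 3.34 without WT replicate 3, where Madcam1 was at 3.62. The stromal and endothelial list did not pass with 1 surrogate variable (adjusted p = 0.0729) or with the plasma cell marker share as a covariate (adjusted p = 0.306).

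Epithelial markers fell (22 of 25 negative, median -1.22, camera adjusted p = 1.7e-05, and adjusted p = 0.532 with an estimated correlation), and the call was lost without WT replicate 4 (adjusted p = 0.0796). Fabp1 was at -1.93 ± 0.64, Reg3b at -2.39 ± 0.83, Alpi at -1.87 ± 0.80 and Cdhr5 at -1.46 ± 0.65. The value of Reg3b rested on WT replicate 4, at 40.3 CPM, and was -0.54 without it (adjusted p = 0.679). Fabp1 was at -2.61 without WT/mut replicate 9. With edgeR 0 epithelial markers passed over the list alone or over all genes, and 4, all lower, had an unadjusted p under 0.05. The share of counts from plasma cell markers was 0.132% ± 0.049 (SD, n = 5) in WT/mut and 0.0507% ± 0.0232 (SD, n = 4) in WT libraries, with an exact permutation p of 0.0397 and an adjusted p of 0.238 over 9 measures. B cell markers held 0.399% ± 0.054 and 0.354% ± 0.046 of counts, myeloid markers 0.0690% ± 0.0208 and 0.0603% ± 0.0126, epithelial markers 0.0307% ± 0.0238 and 0.0781% ± 0.0515, ribosomal protein genes 0.639% ± 0.107 and 0.490% ± 0.104, and mitochondrially encoded genes 3.14% ± 2.68 and 2.58% ± 1.60. None of the 9 measures, which also included the total count, the number of genes with a count and the share of the top 10 genes, passed after adjustment, and 1 had an unadjusted permutation p under 0.05. A single measure could not pass this adjustment, since the smallest possible p was 0.00794. The first principal component held 36.6% of the variance and did not separate the groups after adjustment (exact permutation p = 0.0317, adjusted p = 0.0952 over 3 components). With the 2000 most variable genes it did (adjusted p = 0.0238).

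**Figure D3:**
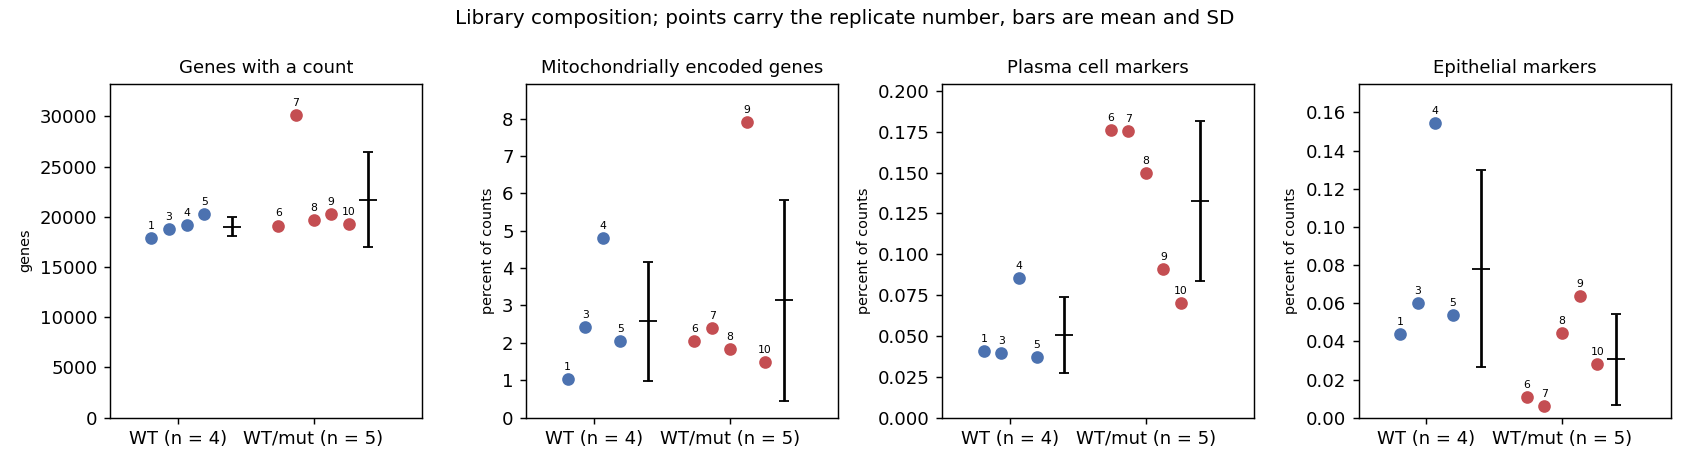
Number of genes with a count and share of counts (percent) from mitochondrially encoded genes, plasma cell markers and epithelial markers in each library, with mean and SD per group beside the points; numbers are replicates and axes start at 0. WT/mut replicate 7 had 30143 genes with a count, WT/mut replicate 9 had 7.90% mitochondrially encoded counts, and WT replicate 4 had 0.155% epithelial marker counts.

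Of the 15 called lists, the red cell, type 17, cholesterol and TGF-beta response lists passed the directional test of fry (adjusted p between 0.00312 and 0.0204), and the other 11 did not (adjusted p between 0.0683 and 0.354). The remaining lists were not called. T cell identity genes had a median of -0.10 (adjusted p = 0.258) and mitochondrially encoded genes a median of 0.28 (adjusted p = 0.412). Naive and recirculating T cell genes (median 0.23, adjusted p = 0.0555) passed without WT/mut replicates 6, 7 or 10 or WT replicate 5, with the size factors of DESeq2, and with genes detected, the epithelial share or the plasma cell share as a covariate. These were 8 of 20 alternatives, with adjusted p down to 0.00359. Markers of myeloid and dendritic cells (median 0.60, adjusted p = 0.0814) passed without WT/mut replicates 9 or 10 or WT replicate 1, without WT/mut replicates 7 and 9 together, with 1 surrogate variable and on ranks. These were 6 of 20 alternatives, with adjusted p down to 0.00135, and with the plasma cell share as a covariate the list passed in the other direction (adjusted p = 2.91e-06). Inhibitory receptors had an adjusted p of 0.185, heat shock and unfolded protein response genes 0.395, homing and adhesion genes 0.412, markers of CD8 T cells 0.645 and the IL-2 and STAT5 response 0.868. The p53 and apoptosis list and the markers of NK, gamma delta and innate lymphoid cells both had an adjusted p of 0.994. The last of these holds Kit beside Blk (1.00 ± 0.47), Fcer1g (0.96 ± 0.54) and Trdc (0.49 ± 0.45). Median and test differed in sign for several of the lists that were not called: camera pointed up with a negative median and mean for the type 1 list and the CD8 T cell markers, and down with a positive median and mean for the regulatory T cell, IL-2, p53 and innate lymphoid lists. For the pathway components the mean was positive with a negative median, and for the homing list it was negative with a positive median. The mast cell and basophil list was not tested, because only Kit and Hdc (-0.66 ± 0.45, adjusted p = 0.550) passed the filter, and the list of Xist and Y-linked genes had 2 genes left.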

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

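Of the tests in this part, those of a lower T cell share and of deeper sequencing were chosen only after the result was seen. In each group, the highest or lowest library was compared with the spread of the others over 220 sets of values (the composition measures and the named genes in each group), and 31 stood apart where chance gives about 11. These sets are not independent, since libraries and gene groups recur. The chance number also assumes normally distributed values. Where a single library of a group has any count, as for Il5, Il13, Il17a and Lrrn1 in WT/mut, it stands apart by construction.

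WT/mut replicate 7 had 30143 genes with a count, against at most 20264 in the other WT/mut libraries, and was highest for Tek (2.54 CPM), Col4a1 (9.57 CPM), Il13 (0.0314 CPM) and Il17a (0.0628 CPM). Deeper sequencing is argued against, since 7 of the other 8 libraries had a higher total. Olfactory and vomeronasal receptor genes, which T cells have no known use for, had a count for 1008 of 1778 genes there and for 37 to 94 in the other libraries, 10.7 times the highest of these, as genomic DNA or diffuse background reads would give. The 7862 genes with a count in that library alone held 0.352% of its counts, with a median count of 5. Of them 11.8% reached 1 CPM, past the 10% set in advance for RNA of another cell type, so that explanation also stays open, although the test does not separate it from background over long genes.

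Markers of cells outside the gate formed the second pattern. WT replicate 4 stood apart in WT with 0.0853% plasma cell marker counts and 0.155% epithelial marker counts, with Igkc at 241 CPM, Reg3b at 40.3 CPM and Alpi at 79.7 CPM. A lower share of T cells in the WT/mut sorts, with the mix of other cells unchanged, would raise the markers of all other cell types alike. The plasma cell and epithelial lists moved apart, with medians differing by 2.70 on the log2 scale (95% bootstrap interval over genes 1.35 to 4.16). This argues against such an even change only. A lower share with a changed mix was not tested, and the interval leaves out the spread between libraries. RNA of plasma cells in differing amounts may contribute. Deviations of Jchain and Igha from their group means ran together over 9 libraries (Pearson r = 0.921, permutation p = 0.00144). The adjusted permutation p was 0.00574 over 4 relations. Spearman rho was 0.833 (permutation p = 0.00827), and r was 0.895 without the 2 libraries farthest from the median. These p-values are approximate, since deviations from group means are not freely exchangeable between the groups. Jchain and Hbb-bs did not run together (r = 0.046, permutation p = 0.904). The sort on CD4, CXCR5 and PD1 would remove plasma cells, the most abundant of these transcripts was Igha at 401 ± 231 CPM in WT/mut, T cells also express some members such as Txndc5 (120 CPM in WT/mut and 122 CPM in WT), and a difference between genotypes in the cells around the Tfh cells stays open and untested.

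WT/mut replicate 9 was highest in its group for mitochondrially encoded genes (7.90% of counts), the share of the top 10 genes (11.3%), Rps16 (148.0 CPM), Rps7 (147.8 CPM), Rps19 (350.3 CPM), Spib (10.1 CPM) and Kif11 (31.5 CPM). WT/mut replicate 6 was highest for Il5 (0.872 CPM) and Iglc1 (125 CPM), WT/mut replicate 8 was highest for Lrrn1 (0.0265 CPM, from 1 count) and lowest for Ifit2 (24.2 CPM), and WT/mut replicate 10 was lowest for Sardh (4.63 CPM) and highest for Trdc (13.8 CPM). In WT, replicate 1 was highest for Nectin3 (38.8 CPM), Ccnb2 (10.6 CPM) and Uqcrc1 (844 CPM) and lowest for Ctla4 (283 CPM), replicate 3 was highest for Il10 (5.13 CPM), Ifng (5.54 CPM) and Foxp3 (77.5 CPM), and replicate 4 was lowest for Pmepa1 (25.0 CPM).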

How the results depend on the processing

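Of the alternatives, 4 were chosen after seeing the data, namely leaving out WT/mut 7 and 9 together, adjusting for the share of epithelial marker counts, adjusting for the share of plasma cell marker counts, and the exact permutation test of list means. The count of 19 genes went to 486 with DESeq2 and 34 with limma-voom with library weights. It was 59 at an adjusted p under 0.1 and 12 with a log2 fold change of at least 1. It was 1 with genes detected as a covariate, 1 without WT/mut 7 and 9 and 1 with the epithelial share as a covariate. With the plasma cell share as a covariate it was 0 with edgeR, and no other tool was run with that covariate. In that fit 496 genes had an unadjusted p under 0.05, fewer than the 776 expected by chance. Leaving out 1 library gave 2 to 23 genes. For each of these the cause was not tested. DESeq2 was run on 34361 genes, over which its median log2 fold change was 0.39. Other size factors, library size only, limma-voom, a non-robust fit, both other filters, 1 surrogate variable and leaving out receptor segments with Xist and Y-linked genes gave 18 to 24 genes, of which 12 to 19 were among the 19. The count of 15 lists went to 1 with an estimated correlation and to 4 with the directional test of fry (its test for change in either direction called 20). It went to 0 with exact permutation of list means, where 7 lists had an unadjusted p under 0.05. A single list could not pass that permutation test after adjustment, so its count of 0 says little. The estimated correlation, fry and the permutation each allow for genes that vary together, and fry, unlike camera, does not compare a list with other genes. The sample separation passed with 2000 genes (adjusted p = 0.0238) and with a variance stabilizing transformation (adjusted p = 0.0476). No measure of library composition passed under any of its alternatives. A single measure could not pass there after adjustment, so this does not show that composition was alike.

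The fold change of Tgfbr1 ranged from -0.221 to 0.0738 over the fits without 1 library. The genes and measures in this paragraph that reversed were not called in the main test, and the cause was not tested. Without 1 library the log2 fold changes ranged from -0.0427 to 3.34 for Col4a1, -0.60 to 1.09 for Ifng, -0.90 to 1.18 for Il10, -0.116 to 0.568 for Il2ra, -0.111 to 0.0788 for Pdcd1, -0.0592 to 0.459 for Smad3, -0.0237 to 0.188 for Tbx21 and -0.139 to 0.037 for Tgfb1. With 1 surrogate variable Tgfbr2 was at -0.0729 and Smad3 at -0.20; Smad3 was at -0.0371 with library weights, Ifng at 0.16 with limma-voom and Col4a1 at -0.39 with genes detected as a covariate. Without WT/mut 7 and 9 Col4a1 was at -0.82 and Pdcd1 at 0.0177. With the epithelial share Il2ra was at -0.16, Tgfb1 at 0.00045 and Pdcd1 at 0.079. With the plasma cell share Pecam1 was at -0.0339, Smad3 at -0.0895, Ctla4 at -0.11, Tgfbr2 at -0.16, Col4a1 at -0.23, Fcer1g at -1.02, Ifng at 0.15 and Hdc at 0.16. The difference of mitochondrially encoded counts ranged from -0.629 to 1.3 percentage points without 1 library, and that of the top 10 genes from -0.93 to 0.644, with -0.0077 on the log2 scale and -0.30 over nuclear genes.

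Some lists turned their direction. Over all 9 fits without 1 library, in some of which they turned, the adjusted p of the pathway components ranged from 0.463 to 0.961, the regulatory T cell list from 0.314 to 0.923, the type 1 list from 0.157 to 0.928 and the type 2 list from 0.658 to 0.945. With CPM of at least 1 in 4 libraries, the type 2 list had 0.887 and the pathway components 0.982. The type 1 list had 0.183 with 1 surrogate variable, 0.404 with genes detected, 0.142 without WT/mut 7 and 9, 0.874 with the epithelial and 0.735 with the plasma cell share, and 0.833 by permutation. The pathway components had 0.974 with fry, 0.840 with the epithelial share and 0.833 by permutation, and the regulatory T cell list had 0.949 on ranks and 0.467 by permutation. Epithelial markers turned with their own share as a covariate (0.0511). With the plasma cell share, oxidative phosphorylation (0.00419) and the myeloid markers (2.91e-06) passed in the other direction, and the type 2 list had 0.892; the cause was not tested. The type 17 list passed in 19 of 20 alternatives, the TGF-beta response, cholesterol and red cell lists in 18 each, and the immediate early list in 7. For Il13 and Il17a, with 1 and 2 counts in all, a difference was not detectable at this depth.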

Other observations

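All genes in this paragraph were chosen after their values were seen. Beyond the 19 called genes, 40 more had an adjusted p under 0.1 and above 0.05. Dbh, the dopamine beta-hydroxylase gene that lies next to Sardh on chromosome 2, was lower in WT/mut cells (-1.65 ± 0.27, adjusted p = 0.0501). Lower values were also found for Tnfrsf8, the gene of the surface receptor CD30 (-0.64 ± 0.11, adjusted p = 0.0649), for the activin-binding protein gene Fst (-1.13 ± 0.20, adjusted p = 0.0649) and for the decoy interleukin 1 receptor gene Il1r2 (-0.58 ± 0.10, adjusted p = 0.0709). Higher values were found for Tsc22d3, a glucocorticoid-induced gene (0.86 ± 0.15, adjusted p = 0.0644), and for the ubiquitin ligase gene Nedd4 (1.05 ± 0.20, adjusted p = 0.0887). None of these passed the threshold.

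Within the IL-2 and STAT5 list, which was not called, 6 of 23 members passed over the list alone and went both ways. Bcl2 (-0.43 ± 0.09), Pim2 (-0.58 ± 0.14), Lta (-0.58 ± 0.14) and Tnfrsf4 (-0.46 ± 0.15) fell, and Ccnd2 (0.34 ± 0.10) and Prdm1 (0.94 ± 0.30) rose, with adjusted p between 0.104 and 0.299 over all genes. In the list of inhibitory receptors Cblb rose (0.54 ± 0.12) and Cd200r1 fell (-0.42 ± 0.11) over the list alone.

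Of the tests below, that of epithelial RNA and both tests of gene position were chosen only after the result was seen. The third pattern was the lower level of TGF-beta response genes in WT/mut cells. Epithelial RNA in the WT libraries is argued against as the whole cause, since with the epithelial marker share as a covariate the list kept its direction and call (median -0.22 against -0.26, camera adjusted p = 0.00102). A lower share of T cell RNA is also argued against, but only as an even fall of all T cell genes. TMM scaling removes a fall shared by most genes, so only the difference between the 2 lists bears on this. The median of T cell identity genes had a 95% bootstrap interval over genes from -0.15 to 0.04, above the list's median of -0.26. That interval leaves out the spread between libraries, and the median of the TGF-beta response list was taken as a point without an interval. An effect of the genotype may remain as a hypothesis, with 2 reservations. The list did not pass with an estimated correlation, and its mean log2 CPM per library did not separate the groups (exact permutation p = 0.222, adjusted p = 0.420).

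For the count of genes, chance in the grouping of the libraries is argued against, though not excluded. Of the 126 splits of the 9 libraries into 5 and 4, 100 were run. With edgeR 1 of these 100, the real one, called as many as 19 genes, and the highest other split called 1. With DESeq2, 1 of 30 splits reached the real 486, the highest other split called 239 genes and the median of the others was 25. For the 15 gene lists, 3 of 100 splits called as many, the real one included. That share is under 0.05, but 2 mixed splits called more, 16 and 17 lists, and the median of the others was 9. Chance is therefore argued against for the count of lists at that level only, and a single list's call with the preset correlation is weak evidence.

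A region carried along with the Tgfbr1 mutation from another strain could hold more changed genes. Within 20 Mb of Tgfbr1 on chromosome 4, 29 of 186 tested genes (15.6%) had an unadjusted p under 0.05, against 12.1% of 15326 elsewhere (odds ratio 1.34, 95% interval 0.867 to 2.01, Fisher's exact p = 0.143). Of the genes called at an adjusted p under 0.05, 0 lay in that window. The called gene Tek, with counts in WT/mut libraries only, lies outside it on the same chromosome, at 94739289 to 94874976. A longer region was not tested. The interval of the odds ratio leaves the question open. Adjacent genes that change together were looked for among the 59 genes at an adjusted p under 0.1. There was 1 such pair, Dbh and Sardh, and 10000 random draws gave a mean of 0.113 pairs (permutation p = 0.108). A single pair could not pass this test, so it cannot decide whether these neighbours changed together by chance.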
